A study of Mus musculus with 15 samples.

How the data were processed

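The series holds liver RNA-seq libraries of C57BL/6 mice in 3 feeding groups of 5 libraries each: ad libitum feeding (AL), intermittent fasting for 16 h (IF16) and every-other-day fasting for 24 h (EOD). Per the labels, the mice were assigned at random, were 3 months of age at the start and 6 months at the end, and had been on the regimen for 3 months. The left lateral lobe was frozen, and mRNA was taken from total RNA with poly-T beads and made into libraries with the NEBNext Ultra kit, per the labels' protocols. The labels do not say that each library is a separate mouse, nor at what hour or how long after the last meal the livers were taken. Every p-value therefore measures the spread between these libraries, which may be partly technical.

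The deposited counts are raw whole numbers per Ensembl gene with 1 column per library. STAR 2.5, HTSeq 0.6.1, DESeq2 and the mouse build mm10 are named in the submitters' processing notes, without a role or an order. The counting mode with respect to strand is not given in the sources used here, so counts of antisense and overlapping genes may be mixed. Counts of close paralogs (the Mup, Cyp4a, Saa and Cyp2c families) could also have been split between copies, and their values are uncertain for that reason. The authors also deposited FPKM values, which equal the count scaled by the gene length in the table and by the library total in 100% of cells at a relative tolerance of 1e-08. The deposited group columns of FPKM are the means of the 5 libraries and were used for a check only. The count table lists 35275 genes, of which 34490 were found by identifier in the reference name table, and 12666 had no count in any library. Coordinates and gene types are those of the deposited table.

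Library totals ranged from 28129883 to 38147534 counts, so that a floor of 3 counts corresponds to 0.0786 to 0.107 CPM (counts scaled to a common library total). Pairs of libraries within a group differed by a chi-square per degree of freedom of 24.9 to 219 over 30 pairs, which excludes counts of 1 library entered under 2 names but not 2 preparations of 1 liver, and n counts libraries, 5 in every group. AL replicates 4 and 5 differed by 32.2, and by 131 to 219 from AL replicates 1 to 3.

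Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the groups and a minimum count of 10, which left 13837 genes. Libraries were scaled by TMM, all 15 libraries entered 1 fit with a mean per group and no other term, and each pair of groups was compared by the quasi-likelihood F test with robust dispersion estimation (glmQLFit and glmQLFTest). Every adjusted p in the text is from this edgeR test with Benjamini-Hochberg adjustment over the tested genes, at a threshold of 0.05, unless another test is named. The common biological coefficient of variation was 0.211. Log2 fold changes are those of the fit, and CPM per library are TMM-scaled. Each SE is the size of the log2 fold change divided by the square root of its F statistic, so it carries the same information as the unadjusted p.

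Before the data were examined, 48 gene lists were fixed for the metabolic pathways of liver, stress and immune responses, organelles and protein complexes, liver zones, sex-biased genes, markers of other cell types and RNA quality. The 43 lists with at least 5 tested members were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. A list is said to be called where it passed in this test. The 5 smaller lists were counted only. Camera compares the genes of a list with the other genes tested. The same lists were tested with the correlation estimated per list and with fry, which asks whether the genes of a list move one way on balance without comparing them with other genes. Over the lists alone, p-values were adjusted within each list. A list score is the mean over its tested genes of log2 CPM after subtraction of each gene's mean over the 15 libraries.

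The genes named in the text follow a rule fixed before the data were examined. It takes the 6 largest increases and the 6 largest decreases of each comparison among protein-coding genes past the threshold with a symbol that is not a gene-model number, a mean of at least 1 CPM and all 5 libraries of the first group on the same side of the mean log2 CPM of the second. It adds up to 3 genes with the smallest p from each list with a member past the threshold, and 1 from each other list. Genes outside the rule are said to be chosen after their values were seen.

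The alternatives were DESeq2 size factors in edgeR, the DESeq2 1.42.0 Wald test, no filter on low counts, a filter of 1 CPM in 5 libraries, the 2 groups of a comparison alone, the replicate number as a block, each library left out in turn, and limma on log2 of the deposited FPKM plus 1 or plus 0.1 with a minimum mean of 0.5 or none. Leaving out AL replicates 4 and 5 together, and removing the mitochondrially encoded genes before scaling, were added after the data were seen. IF16 and EOD were compared with the same 5 AL libraries. For that reason 20 simulations of unchanged groups that share 1 simulated AL group were run beside the observed agreement of the fasting effects. All 15 libraries were drawn there from the AL means, without correlation between genes. The AL libraries were also split between the comparisons in 20 ways. The tests were also run on 100 splits of the 10 libraries of each comparison.

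The test was run on simulated counts for the real genes and library sizes, with 200 changed genes of known fold. For IF16 versus AL, 13722 simulated genes were tested and 31.3%, 76.1% and 89.4% of the genes changed by 1.5, 2 and 4 fold were recovered, with 5.8% false calls. For EOD versus AL, over 13733 genes, the shares were 27.3%, 71.6% and 93.9%, with 5.9% false calls. For EOD versus IF16, over 13744 genes, they were 25.8%, 71.6% and 92.2%, with 1.6% false calls. Changes of 1.5 fold were thus missed more often than found where 200 genes were changed. Where many more genes change, the adjusted threshold is less strict, so these shares need not hold for the real comparisons with EOD. Simulated lists with no shift, 40 in EOD versus AL over 13748 genes, gave 0 calls with camera, in counts drawn without correlation between genes.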

Results

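Messenger RNA of the liver was sequenced from 15 libraries of C57BL/6 mice, 5 fed ad libitum (AL), 5 under 16-h intermittent fasting (IF16) and 5 under every-other-day fasting (EOD), to compare liver gene expression between the feeding regimens. Totals ran from 28129883 to 33383641 counts in AL, from 31362642 to 38147534 in IF16 and from 29581097 to 37802749 in EOD (n = 5 each). The 10 most abundant genes took 23.74%, 25.08% and 21.46% of the counts in AL, IF16 and EOD. Mitochondrially encoded transcripts took 11.49% of the counts in AL (SD 2.16, n = 5), 10.38% in IF16 (SD 1.11) and 6.888% in EOD (SD 1.87), and EOD replicate 5, at 10.08%, stood apart from the other EOD libraries. The first principal component held 35.1% of the variance and placed the EOD libraries at 20.1 to 48.4 and the AL libraries at -41.7 to -24. The second held 14.5% and placed AL replicates 4 and 5 at -45.7 and -38.5, below every other library.

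AL replicates 4 and 5 carried high acute phase transcripts. Saa1, which encodes serum amyloid A, was measured at 2810 and 5610 CPM in these libraries and at 27.9 to 30.5 CPM in AL replicates 1 to 3. The score of the acute phase list was 1.73 and 2.17 in them and between -0.55 and -0.04 in the other 13 libraries. Their scores were also low for sinusoidal endothelium (-0.81 and -0.95), female-biased genes (-1.38 and -1.82), B and plasma cells (-0.7 and -0.66), fatty acid oxidation (-0.92 and -1.24), xenobiotic metabolism (-0.43 and -0.55), stellate cells (-0.52 and -0.5) and lipid droplets (-0.57 and -0.45). They were high for male-biased genes (0.95 and 0.59, other AL libraries -0.31 to 0.02), NRF2 targets (0.39 and 0.38, others -0.17 to -0.13) and the unfolded protein response (0.39 and 0.53, others -0.29 to 0.23).

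**Figure D1:**
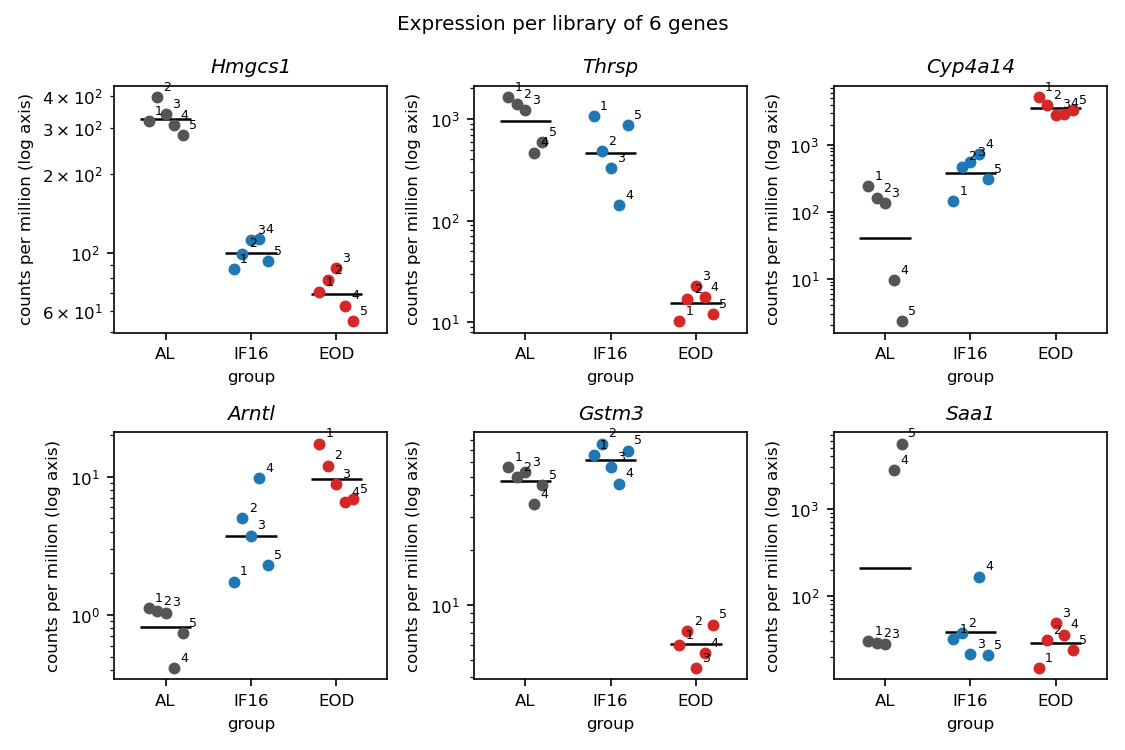
Expression per library of Hmgcs1, Thrsp, Cyp4a14, Arntl, Gstm3 and Saa1 in CPM on a log axis, with 1 point per library numbered by replicate and a bar at the geometric mean of the 5 libraries of a group. Hmgcs1 lay at 283 to 395 CPM in AL and at 54.7 to 87.3 CPM in EOD, and Saa1 was high in AL replicates 4 and 5.

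The first comparison asked what 16-h fasting changed. Genes of cholesterol synthesis were lower in IF16 than in AL. Hmgcs1, which makes the HMG-CoA of the mevalonate pathway (chromosome 13, 119690462 to 119708086, mm10), fell from 329 CPM (SD 42, n = 5) to 101 CPM (SD 11.6, n = 5), a log2 fold change of -1.71 (SE 0.13, adjusted p = 2.19e-06). Mvd, a decarboxylase of the same pathway, fell 4.47 fold (adjusted p = 9.11e-05), and Lss, which closes the sterol rings, fell 2.17 fold (adjusted p = 0.000472). Of the 25 genes of the list, 17 fell and none rose, with 21 lower when adjusted over the list alone. The median log2 fold change was -1.01 (camera adjusted p = 1.99e-23, and adjusted p = 0.298 with an estimated correlation).

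Fatty acid oxidation and PPARA target genes moved the other way. Of 39 genes, 8 rose and 2 fell (16 and 2 when adjusted over the list alone), with a median of 0.36 (camera adjusted p = 8.98e-09, and adjusted p = 0.651 with an estimated correlation). Acot1, an acyl-CoA thioesterase, rose 3.71 fold (SE of log2 0.32, adjusted p = 0.00561), and Cyp4a31, a fatty acid hydroxylase, rose 2.95 fold (adjusted p = 0.00728). Cidec, a lipid droplet protein in the list, fell 3.03 fold (adjusted p = 0.0116). The score of the list was -0.92 and -1.24 in AL replicates 4 and 5 and -0.45 to -0.13 in AL replicates 1 to 3. In the lipogenic list, 2 of 24 genes fell (7 when adjusted over the list alone), with a median of -0.38 (camera adjusted p = 0.000157, and adjusted p = 0.651 with an estimated correlation). Its scores were 0.35 and 0.25 in AL replicates 4 and 5, 0.79 to 1.26 in the other AL libraries and -0.17 to 0.5 in IF16. They were Pnpla3, a lipid droplet lipase homolog, at a log2 fold change of -3.16 (SE 0.7, adjusted p = 0.0242), and Srebf1, the regulator of lipogenesis, at -1.34 (SE 0.34, adjusted p = 0.0441). Pnpla3 was at -2.05 without AL replicate 2 and lost its call without IF16 replicate 2, 3, 4 or 5 (adjusted p up to 0.07), and Srebf1 kept its call only without AL replicate 4 or 5, IF16 replicate 1 or EOD replicate 3, 4 or 5 (adjusted p up to 0.115 otherwise). Plin5, a perilipin of lipid droplets, rose 2.01 fold (adjusted p = 0.0139), and Angptl4, a lipase inhibitor, rose 2.12 fold (adjusted p = 0.0253). Of 25 lipoprotein and lipid transport genes, Angptl4 alone rose and 1 fell, by 3.89 fold (adjusted p = 0.0173). That list did not pass with camera (camera adjusted p = 0.0737). The call of Plin5 ended without AL replicates 4 and 5 (adjusted p = 0.0535), and that of Angptl4 without AL replicate 2 or IF16 replicate 2, 3, 4 or 5 (adjusted p up to 0.0739).

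The 6 largest increases that met the naming rule were those of Tcf24, Arntl, Xlr3a, Pcp4l1, Lonrf3 and Lepr. Tcf24, a basic helix-loop-helix factor (chromosome 1, 9960163 to 9967932), rose 10.6 fold from 0.156 CPM (SD 0.102) to 1.7 CPM (SD 0.594; adjusted p = 0.00114). Its AL level lay near the floor of 3 counts, so this fold is uncertain. Arntl, the clock activator BMAL1 (chromosome 7, 113207465 to 113314122), rose 5.1 fold (log2 SE 0.47, adjusted p = 0.0127). Its IF16 libraries ranged from 1.74 to 9.74 CPM, and its call ended without AL replicates 4 and 5 (log2 fold change 2.07, adjusted p = 0.0692). Lepr, the leptin receptor, rose 3.85 fold (adjusted p = 0.00551), Pcp4l1 3.99 fold (adjusted p = 0.000119) and Lonrf3 3.98 fold (adjusted p = 0.00129). Xlr3a rose 4.45 fold (adjusted p = 0.0478), a call kept only without AL replicate 4, IF16 replicate 1 or 3, or EOD replicate 1 (adjusted p up to 0.111 otherwise; 0.0657 without AL replicates 4 and 5 together).

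The 6 largest decreases that met the naming rule were those of Mup17, Lcn2, Hcar2, Gprc5b, Cfd and S100a8. Gprc5b, an orphan receptor, fell 14.6 fold (log2 SE 0.69, adjusted p = 0.0069). Its IF16 libraries, at a log2 CPM of -2.71 to -1.73, lay near the floor of 3 counts, so this fold is uncertain. Cfd, complement factor D, fell 10.1 fold (log2 SE 0.65, adjusted p = 0.0113). Cfd was at 0.795 and 0.979 CPM in AL replicates 4 and 5 and at 7.31 to 8.64 CPM in AL replicates 1 to 3. Mup17, a major urinary protein with near-identical copies, fell 93.1 fold (log2 SE 1.57, adjusted p = 0.0403). Lcn2, an acute phase lipocalin, fell 44.9 fold (log2 SE 1.36, adjusted p = 0.0459) and was at 214 and 464 CPM in AL replicates 4 and 5 and at 4.14 to 4.99 CPM in the other AL libraries. S100a8, a neutrophil calcium-binding protein, fell 9.29 fold (adjusted p = 0.0491), and Hcar2, the hydroxycarboxylic acid receptor, fell 18.9 fold (adjusted p = 0.018), with AL replicates 4 and 5 at 8.5 and 6.14 CPM. Without AL replicates 4 and 5 the log2 fold changes were -0.55 for Lcn2 (adjusted p = 0.473), -0.54 for S100a8 (0.511), -1.91 for Hcar2 (0.0897) and -5.81 for Mup17 (0.104). Leaving out 1 library ended the call of Lcn2 and S100a8 unless it was AL replicate 1, 2 or 3 (adjusted p up to 0.123 and 0.118). It ended that of Mup17 for AL replicate 1, 2, 4 or 5 and each IF16 library (up to 0.115), and that of Hcar2 for IF16 replicate 3 or 5 (up to 0.0567). The log2 fold change was -4.21 for Lcn2 without AL replicate 5, and -2.54 for S100a8 and -3.53 for Hcar2 without AL replicate 4.

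Markers of sinusoidal endothelium were higher in IF16. Of 16 genes, 7 rose and none fell, with 15 higher when adjusted over the list alone and a median of 0.6 (camera adjusted p = 1.04e-12, and adjusted p = 0.372 with an estimated correlation). Clec4g and Lyve1, endothelial surface lectin and hyaluronan receptor, rose 1.82 fold (adjusted p = 0.00164) and 2.24 fold (adjusted p = 0.00396), and Mrc1, the mannose receptor, rose 1.83 fold (adjusted p = 0.00324). The score of this list was -0.81 and -0.95 in AL replicates 4 and 5, -0.36 to -0.09 in the other AL libraries and 0.12 to 0.37 in IF16. Of 53 genes of xenobiotic metabolism, 8 rose and 1 fell (15 and 3 when adjusted over the list alone), with a median of 0.3 (camera adjusted p = 2.12e-07, and adjusted p = 0.372 with an estimated correlation). Cyp2c54 and Cyp2c37, cytochromes P450 with close copies, rose 2.07 fold (adjusted p = 0.000472) and 2.08 fold (adjusted p = 8e-04), and the AL 4 and 5 scores of the list were -0.43 and -0.55. Of 18 female-biased genes, 2 rose and 2 fell (4 and 3 when adjusted over the list alone), with a median of 0.46 (camera adjusted p = 0.0095, and adjusted p = 0.836 with an estimated correlation). The scores of AL replicates 4 and 5 were -1.38 and -1.82, and the call ended without either of them (adjusted p = 0.0747 and 0.0894) or both (0.734).

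Genes of the interferon, acute phase and immediate early lists were lower in IF16. Of 31 interferon response genes, 4 fell (9 when adjusted over the list alone), with a median of -0.36 (camera adjusted p = 7.24e-07, and adjusted p = 0.651 with an estimated correlation). Oasl1, an interferon-induced synthetase-like protein, fell 2.06 fold (adjusted p = 0.00745), and Isg15, a ubiquitin-like modifier, fell 1.72 fold (adjusted p = 0.0173; 0.0737 without AL replicates 4 and 5). Of 25 acute phase genes, 1 fell, Lcn2 (1 higher and 11 lower when adjusted over the list alone), with a median of -0.78 (camera adjusted p = 0.00309, and adjusted p = 0.858 with an estimated correlation). Saa2 did not pass, at -6.22 (SE 1.63, adjusted p = 0.0582; -4.6 without AL replicate 5). The call of the list ended without AL replicate 4 (adjusted p = 0.146) or 5 (0.228), and its median turned to 0.22 without both. Of 23 immediate early genes, 3 fell (1 higher and 10 lower when adjusted over the list alone), with a median of -0.62 (camera adjusted p = 0.000166, and adjusted p = 0.651 with an estimated correlation). Fos, a subunit of AP-1, fell 2.69 fold (adjusted p = 0.027) and Atf3, a stress-induced factor, 2.3 fold (adjusted p = 0.0306). The call of Fos ended without AL replicate 2 or 4 or IF16 replicate 2, 3, 4 or 5 (adjusted p up to 0.0739; 0.058 without AL replicates 4 and 5 together), and that of Atf3 without AL replicate 1, 2 or 4 or IF16 replicate 1, 3, 4 or 5 (up to 0.0857). The scores in this list were 1 and 0.75 in AL replicates 4 and 2, 0.22, -0.24 and 0.04 in AL replicates 1, 3 and 5, and -0.41 to -0.02 in IF16.

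Proteasome genes were lower in IF16, with 4 of 30 fallen (6 when adjusted over the list alone) and a median of -0.11 (camera adjusted p = 0.000208, and adjusted p = 0.81 with an estimated correlation; 0.0548 without AL replicates 4 and 5). Psmd14, a deubiquitinase of the lid, fell 1.44 fold (adjusted p = 0.0248), a call that ended without AL replicate 1, 4 or 5 or IF16 replicate 3, 4 or 5 (up to 0.0653; 0.129 without AL replicates 4 and 5 together). Of 26 genes of the unfolded protein response, 1 fell, Calr, a chaperone of the endoplasmic reticulum, at 1.66 fold (adjusted p = 0.00925; 0.0597 without AL replicates 4 and 5), with 1 higher and 4 lower when adjusted over the list alone. The share past the threshold in this list is near the 3.5% of all tested genes. The median of that list was -0.15 (camera adjusted p = 0.0244, and adjusted p = 0.858 with an estimated correlation), and its call ended without AL replicate 3, 4 or 5 or IF16 replicate 1, 2 or 3 (0.0512 to 0.174), and without AL replicates 4 and 5 together (0.63). Among 45 ribosomal protein genes, Rps27 alone rose, 1.44 fold (adjusted p = 0.0384), with 11 higher when adjusted over the list alone and a median of 0.27 (camera adjusted p = 1.52e-10, and adjusted p = 0.651 with an estimated correlation). Rps27 kept its call only without IF16 replicate 1 or EOD replicate 1, 3, 4 or 5 (up to 0.127 otherwise). No gene of nuclear-encoded oxidative phosphorylation (41 tested) or of the heat shock response (19 tested) passed in edgeR, over all genes or when adjusted over the list alone, with 17 and 2 genes at an unadjusted p under 0.05. Their medians were 0.23 (camera adjusted p = 8.28e-08, and adjusted p = 0.651 with an estimated correlation) and 0.1 (camera adjusted p = 0.0388, and adjusted p = 0.858 with an estimated correlation). The heat shock call ended without AL replicate 1 (0.272) or 2 (0.408) or IF16 replicate 4 (0.118) or 5 (0.213).

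Of the clock genes, Cry1, a repressor, rose 2.71 fold (adjusted p = 0.000504) and Bhlhe41, another repressor, fell 5.64 fold (adjusted p = 0.00051). In the list of 24, 3 rose and 1 fell (5 and 4 when adjusted over the list alone), and the list did not pass with camera (median -0.22, camera adjusted p = 0.394). Igfbp2, a binding protein of insulin-like growth factors, rose 2.14 fold (adjusted p = 0.000793). Txnip, a thioredoxin inhibitor that restrains glucose uptake, rose 3.12 fold (adjusted p = 0.0147; 0.0612 without AL replicates 4 and 5).

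In all, 484 of 13837 genes differed between IF16 and AL (194 higher, 290 lower), of which 161 by at least 2 fold, and 14 of 43 lists were called (7 up, 7 down). The number of genes was 269, 241 and 254 without IF16 replicates 2, 3 and 5, and 368 without AL replicates 4 and 5. With an estimated correlation 0 lists passed (camera, lowest adjusted p 0.298, 3 lists at an unadjusted p under 0.05), and with fry 3 did. These were cholesterol synthesis (fry adjusted p = 0.0024), sinusoidal endothelium (0.0133) and xenobiotic metabolism (0.0167). The other lists called with camera did not pass with fry (fry adjusted p from 0.148 to 0.508).

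**Figure D2:**
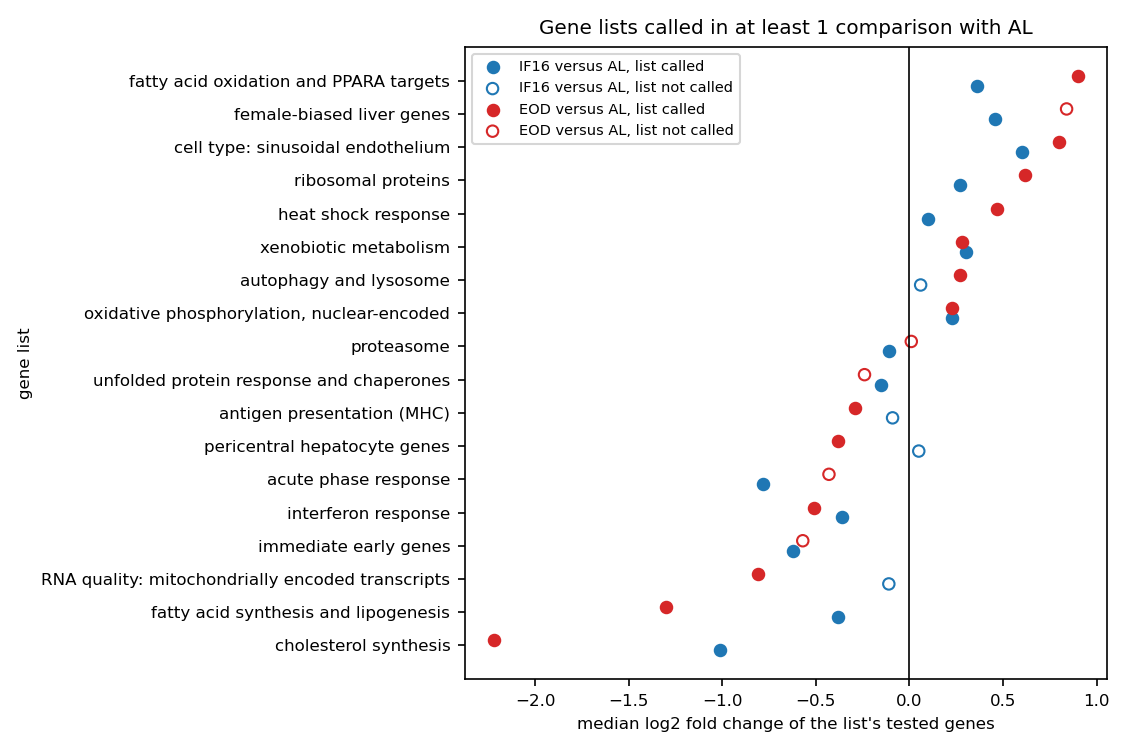
Median log2 fold change of the tested genes of each of the 18 gene lists called in at least 1 comparison with AL, for IF16 versus AL and EOD versus AL. Filled points are lists past an adjusted p of 0.05 with camera, and cholesterol synthesis has the lowest medians, -1.01 and -2.22.

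The second comparison asked what every-other-day fasting changed. Genes of cholesterol synthesis and lipogenesis were lower and those of fatty acid oxidation higher in EOD than in AL. Dhcr7, which makes cholesterol from its last precursor (chromosome 7, 143823145 to 143848410), fell from 115 CPM (SD 16.2, n = 5) to 11.8 CPM (SD 2.63, n = 5), a log2 fold change of -3.29 (SE 0.19, adjusted p = 8.43e-09). Thrsp, a lipogenic spot protein (chromosome 7, 97412938 to 97417730), fell from 1070 CPM (SD 514) to 15.9 CPM (SD 5), a log2 fold change of -6.07 (SE 0.6, adjusted p = 1.17e-05). Cyp4a14, a PPARA-driven fatty acid hydroxylase (chromosome 4, 115486200 to 115496142), rose from 110 CPM (SD 104) to 3640 CPM (SD 960), a log2 fold change of 5.04 (SE 1.02, adjusted p = 0.00232). In AL replicates 4 and 5 Cyp4a14 was at 9.44 and 2.3 CPM, against 136 to 245 CPM in AL replicates 1 to 3.

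Of 25 cholesterol synthesis genes, 23 fell and none rose, the same number when adjusted over the list alone, with a median of -2.22 (camera adjusted p = 3.06e-19, and adjusted p = 0.525 with an estimated correlation). Hmgcs1 fell 4.64 fold (adjusted p = 9.83e-09) and Lss 5.04 fold (adjusted p = 1.33e-08). Of 24 lipogenic genes, 16 fell and 1 rose, as when adjusted over the list alone, with a median of -1.3 (camera adjusted p = 1.4e-09, and adjusted p = 0.616 with an estimated correlation). Acaca, the acetyl-CoA carboxylase, fell 5.07 fold (adjusted p = 2.55e-06), Acss2, an acetyl-CoA synthetase, 5.02 fold (adjusted p = 1.29e-06) and Dak, a triose kinase, 4.82 fold (adjusted p = 8.43e-09). Of 39 genes of fatty acid oxidation and PPARA targets, 32 rose and 3 fell, as when adjusted over the list alone, with a median of 0.9 (camera adjusted p = 2.97e-13, and adjusted p = 0.616 with an estimated correlation). Acot1 rose 17.6 fold (adjusted p = 1.84e-06), Cyp4a31 14.9 fold (adjusted p = 2.73e-07), Cyp4a10 14.8 fold (adjusted p = 0.000618) and Slc22a5, the carnitine transporter, 3.43 fold (adjusted p = 3.59e-07). The scores of AL replicates 4 and 5 in this list were -0.92 and -1.24, and without them Cyp4a14 was 20.6 fold higher. Of 8 ketone body genes, 4 rose and 1 fell, as when adjusted over the list alone, and the list did not pass with camera (median 0.44, camera adjusted p = 0.119) but did with fry (adjusted p = 0.00567). Slc16a1, a ketone and lactate transporter, rose 3.48 fold (adjusted p = 5.52e-06) and Bdh2 fell 1.85 fold (adjusted p = 5.55e-05). Pklr, liver pyruvate kinase, fell 7.33 fold (adjusted p = 2.14e-05), and Gys2, liver glycogen synthase, fell 2.24 fold (adjusted p = 0.000145). Plin5 rose 4.29 fold (adjusted p = 4.26e-06).

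By the same rule, the 6 largest increases were those of Cyp4a14, Acot1, Cyp4a31, Cyp4a10, Tcf24 (12.7 fold, adjusted p = 4.19e-05) and Arntl (11.7 fold, adjusted p = 7.03e-05). The 6 largest decreases by that rule were those of Saa2, Thrsp, Cyp21a1, Saa1, Selenbp2 and Lcn2. Cyp21a1, a steroid hydroxylase, fell 59.3 fold (log2 SE 0.96, adjusted p = 0.000379), with AL libraries at 0.544 to 7.19 CPM. Selenbp2, a selenium-binding protein, fell 42.2 fold (log2 SE 1.07, adjusted p = 0.00209), with AL replicates 4 and 5 at 664 and 565 CPM and the other AL libraries at 17.2 to 105 CPM. Saa2 (log2 fold change -7.23, SE 1.71, adjusted p = 0.00631), Saa1 (-5.79, SE 1.6, adjusted p = 0.0143) and Lcn2 (-5.34, SE 1.35, adjusted p = 0.00907) are acute phase genes high in AL replicates 4 and 5. Without these libraries their log2 fold changes were -0.78 (adjusted p = 0.158), 0.11 (0.919) and -0.38 (0.446), and without AL replicate 5 alone -5.6, -4.55 and -4.05. Selenbp2 was at -4.77 without AL replicate 4, with AL replicate 5 still in the fit. The AL mean behind its fold rests largely on these 2 libraries, so the fall from the other AL libraries was smaller. Of 25 acute phase genes, 2 rose and 10 fell, as when adjusted over the list alone, and the list did not pass with camera (median -0.43, camera adjusted p = 0.542). Serpina3m, a serine protease inhibitor, rose 1.95 fold (adjusted p = 7.76e-05).

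Ribosomal protein transcripts were higher and mitochondrially encoded transcripts lower in EOD. Of 45 ribosomal protein genes, 40 rose and none fell (42 when adjusted over the list alone), with a median of 0.62 (camera adjusted p = 1.22e-14, and adjusted p = 0.616 with an estimated correlation). Rps27 and Rps9, of the small subunit, each rose 2.11 fold (adjusted p = 2.47e-05 and 2.9e-05). Of 12 mitochondrially encoded genes, 11 fell (12 when adjusted over the list alone), with a median of -0.81 (camera adjusted p = 1.8e-06, and adjusted p = 0.616 with an estimated correlation). The cytochrome oxidase subunit mt-Co2 fell 2.08 fold (adjusted p = 5.33e-05) and the ATP synthase subunit mt-Atp6 2.14 fold (adjusted p = 0.000231). The score of EOD replicate 5 for this list was 0.03, against -0.78 to -0.6 in the other EOD libraries. Of 41 nuclear genes of oxidative phosphorylation, 15 rose and 1 fell (16 and 1 when adjusted over the list alone), with a median of 0.23 (camera adjusted p = 0.00215, and adjusted p = 0.77 with an estimated correlation). Ndufb8, of complex I, rose 2.25 fold (adjusted p = 0.000166). EOD replicate 5 was also low for oxidative phosphorylation (-0.19, other EOD libraries 0.02 to 0.24, AL -0.21 to -0.1) and ribosomal proteins (-0.05, other EOD libraries 0.22 to 0.6, AL -0.52 to -0.19).

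Genes of the interferon and antigen presentation lists were lower and those of the heat shock list higher. Of 31 interferon genes, 17 fell and 1 rose, as when adjusted over the list alone, with a median of -0.51 (camera adjusted p = 0.000446, and adjusted p = 0.616 with an estimated correlation). Gbp7, a guanylate-binding protein, fell 2.51 fold (adjusted p = 6.09e-05) and Oasl1 2.48 fold (adjusted p = 0.000111). Of 19 genes of antigen presentation, 9 fell, as when adjusted over the list alone, with a median of -0.29 (camera adjusted p = 0.000579, and adjusted p = 0.616 with an estimated correlation). Tap2, a peptide transporter, fell 2.43 fold (adjusted p = 3.13e-06) and Psmb9, an immunoproteasome subunit, 2.62 fold (adjusted p = 5.1e-06). For interferon genes EOD replicate 5 was at a score of 0.2, within the AL range of -0.06 to 0.59, and the other EOD libraries at -0.65 to -0.05. For antigen presentation EOD replicates 4 and 5 were at 0.06 and -0.01, within the AL range of 0 to 0.35 or next to it, and EOD replicates 1 to 3 at -0.68 to -0.32. The scores of T and NK cell markers in EOD replicates 1 to 5 were -0.3, -0.37, -0.13, -0.09 and 0.16. Of 19 heat shock genes, 11 rose (12 when adjusted over the list alone), with a median of 0.47 (camera adjusted p = 0.00157, and adjusted p = 0.616 with an estimated correlation). Hspa8 and Hsp90ab1, constitutive chaperones, rose 1.77 fold (adjusted p = 0.000577) and 1.55 fold (adjusted p = 0.00107). EOD replicate 5 was at a score of -0.08 for heat shock (other EOD libraries 0.17 to 0.44) and -0.04 for autophagy (0.15 to 0.27), and AL replicates 4 and 5 at 0.09 and 0.04 for heat shock (other AL libraries -0.73 to -0.14). Of 26 genes of the unfolded protein response and chaperones, 5 fell and none rose, as when adjusted over the list alone, and the list did not pass with camera (median -0.24, camera adjusted p = 0.2). Of 32 genes of autophagy and lysosome, 14 rose and 4 fell (14 and 5 when adjusted over the list alone), with a median of 0.27 (camera adjusted p = 0.0461, and adjusted p = 0.616 with an estimated correlation). Gabarapl1 and Map1lc3b, of the autophagosome, rose 2.82 fold (adjusted p = 1.84e-06) and 1.93 fold (adjusted p = 1.64e-05). That list's call ended without AL replicate 2 (0.0765), IF16 replicate 1 (0.0524) or EOD replicate 1 (0.0566), 3 (0.0565) or 4 (0.0532). Gadd45b, a growth arrest gene, rose 8.65 fold (adjusted p = 8.68e-05).

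Of 16 markers of sinusoidal endothelium, 12 rose and none fell (13 when adjusted over the list alone), with a median of 0.8 (camera adjusted p = 8.48e-06, and adjusted p = 0.616 with an estimated correlation). Mrc1 rose 2.16 fold (adjusted p = 3.31e-05) and Lyve1 2.69 fold (adjusted p = 5.89e-05), with AL replicates 4 and 5 at scores of -0.81 and -0.95. Of 53 xenobiotic genes, 24 rose and 9 fell (25 and 11 when adjusted over the list alone), with a median of 0.28 (camera adjusted p = 0.037, and adjusted p = 0.616 with an estimated correlation). Cyp3a11 rose 3.16 fold (adjusted p = 1.35e-06), and Gstm3, a glutathione transferase (chromosome 3, 107963696 to 107969283), fell 7.73 fold (adjusted p = 8.43e-09). The xenobiotic call ended without AL replicate 4 (0.0768), 5 (0.0713) or both (0.224), or without EOD replicate 3 (0.0565). Of 21 pericentral hepatocyte genes, 3 rose and 9 fell (3 and 11 when adjusted over the list alone), with a median of -0.38 (camera adjusted p = 0.0437, and adjusted p = 0.616 with an estimated correlation). Cyp1a2, a P450 of that zone, fell 2.18 fold (adjusted p = 6.48e-06), and the call of the list ended without AL replicate 1 (0.0639) or EOD replicate 4 (0.0678). Of 24 clock genes, 5 rose and 10 fell, as when adjusted over the list alone, and the list did not pass with camera (median -0.53, camera adjusted p = 0.0852) but did with fry (adjusted p = 0.009). Clock rose 2.9 fold (adjusted p = 5.52e-06) and Bhlhe41 fell 6.37 fold (adjusted p = 1.83e-05). Igfbp2 rose 3.75 fold (adjusted p = 2.74e-07).

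In all, 4867 of 13837 genes differed between EOD and AL (2430 higher, 2437 lower), of which 1138 by at least 2 fold, and 13 of 43 lists were called (7 up, 6 down). With an estimated correlation 0 lists passed (camera, lowest adjusted p 0.525, 2 lists at an unadjusted p under 0.05), and with fry 20 did, among them the 13 called lists.

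Both fasting regimens were then compared for agreement. Of the 484 genes called in IF16 versus AL, 407 were called in EOD versus AL in the same direction (162 higher, 245 lower), 5 in opposite directions and 72 in IF16 alone. Independent lists of these sizes would share 34.1 higher and 51.1 lower genes. Across genes, which are not independent replicates, the log2 fold changes of the regimens correlated at 0.701. In simulations of unchanged groups that share 1 simulated AL group, the correlation was 0.504. The covariance was 0.202 against 0.0304 in the simulations, a difference of 0.172. The same sign was found in 74.6% of genes, against 66.8% in the simulations. With the AL libraries split between the comparisons, the mean correlation was 0.462 (0.229 to 0.632), the mean covariance 0.149 (SD 0.031) and the mean number of shared genes 144 (43 to 376). The shared genes numbered 229, 212 and 228 without IF16 replicates 2, 3 and 5.

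**Figure D3:**
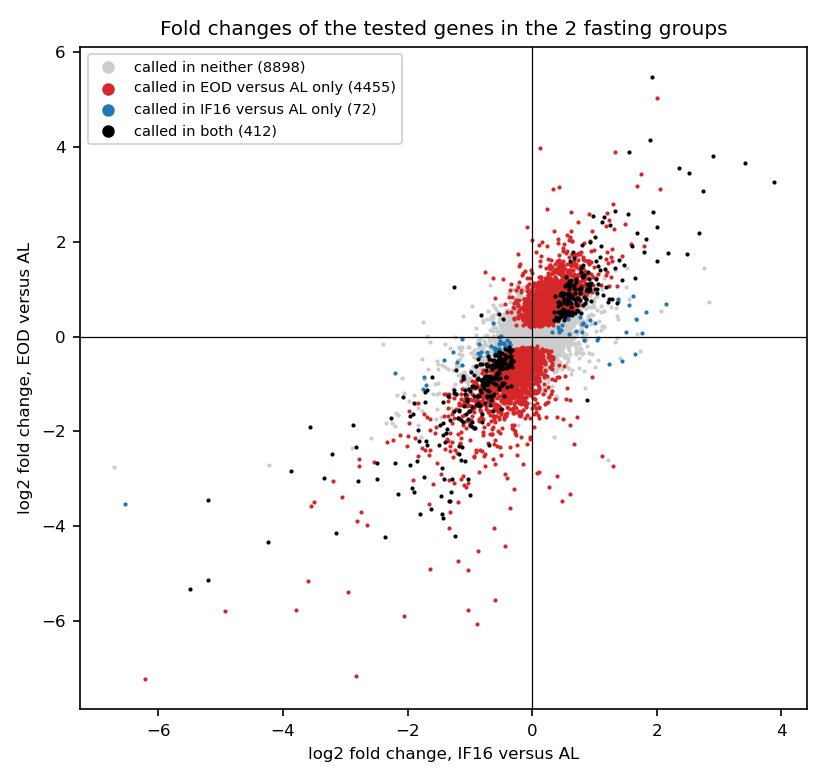
Log2 fold changes of the 13837 tested genes in IF16 versus AL (horizontal) and EOD versus AL (vertical), with 1 point per gene coloured by the comparisons in which it was called. The 412 genes called in both lie along a rising diagonal except for 5 of opposite sign, and both axes share the AL libraries.

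The third comparison set EOD against IF16, regimens that differ in schedule as well as in the length of the fast, which were not separated here. The hour of sampling and the time since the last meal, which the labels do not give, were not separated from the regimen in any comparison. Cholesterol and lipogenic genes were lower and fatty acid oxidation genes higher in EOD than in IF16. Thrsp fell from 577 CPM (SD 380, n = 5) in IF16 to 15.9 CPM (SD 5, n = 5) in EOD, a log2 fold change of -5.18 (SE 0.58, adjusted p = 0.000111). Gstm3 fell from 62.8 CPM (SD 11.7) to 6.18 CPM (SD 1.31), a log2 fold change of -3.34 (SE 0.18, adjusted p = 3.9e-09). Gadd45b (chromosome 10, 80930091 to 80932204) rose from 2.59 CPM (SD 1.03) to 17.7 CPM (SD 8.73), a log2 fold change of 2.77 (SE 0.41, adjusted p = 0.000573).

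Of 25 cholesterol synthesis genes, 16 fell and none rose (19 when adjusted over the list alone), with a median of -0.88 (camera adjusted p = 2.87e-12, and adjusted p = 0.652 with an estimated correlation). Dhcr7 fell 3.96 fold (adjusted p = 4.21e-06), and Nsdhl and Fdps, enzymes of the same pathway, fell 5.11 fold (adjusted p = 1.39e-05) and 5.31 fold (adjusted p = 1.77e-05). Of 24 lipogenic genes, 13 fell (14 when adjusted over the list alone), with a median of -0.97 (camera adjusted p = 1.89e-09, and adjusted p = 0.652 with an estimated correlation). Dak fell 4.55 fold (adjusted p = 1.03e-08), Acaca 3.96 fold (adjusted p = 4.59e-05) and Acss2 3.52 fold (adjusted p = 4.81e-05). Of 39 fatty acid oxidation genes, 21 rose and 1 fell (27 and 1 when adjusted over the list alone), with a median of 0.52 (camera adjusted p = 3.25e-10, and adjusted p = 0.702 with an estimated correlation). Cyp4a31 rose 5.04 fold (adjusted p = 5.25e-05) and Slc22a5 2.17 fold (adjusted p = 0.000102). Of 19 lipid droplet genes, 3 rose (4 when adjusted over the list alone), with a median of 0.32 (camera adjusted p = 0.0451, and adjusted p = 0.702 with an estimated correlation), Plin5 by 2.14 fold (adjusted p = 0.00247) and Plin2 by 1.94 fold (adjusted p = 0.0123). The share in this list is near the 16.1% of all tested genes past the threshold in this comparison. The lipid droplet call ended without AL replicate 2 (0.0681), IF16 replicate 1 (0.0774), 4 (0.06) or 5 (0.0667), or EOD replicate 1 (0.0958), 3 (0.0693) or 4 (0.0546), and with the mitochondrial genes removed (0.0525).

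Of 22 genes of glycolysis, 1 rose and 6 fell (1 and 7 when adjusted over the list alone), with a median of -0.26 (camera adjusted p = 0.0451, and adjusted p = 0.702 with an estimated correlation). Pklr fell 7.73 fold (adjusted p = 7.05e-05) and Slc2a2, the hepatocyte glucose transporter, 2.29 fold (adjusted p = 0.000165). Of 16 glycogen genes, 1 rose and 3 fell (1 and 6 when adjusted over the list alone), with a median of -0.3 (camera adjusted p = 0.0393, and adjusted p = 0.652 with an estimated correlation). Gys2 fell 2.31 fold (adjusted p = 0.000336) and Pygl, glycogen phosphorylase, 1.89 fold (adjusted p = 0.000287). The glycolysis call ended without AL replicate 2 (0.0751), IF16 replicate 2 (0.0684) or 5 (0.0676), or EOD replicate 1 (0.0527), 2 (0.0703) or 5 (0.0814), and the glycogen call without IF16 replicate 2 (0.0662) or EOD replicate 5 (0.0684). Of the 8 ketone body genes, 3 rose and 1 fell (4 and 1 when adjusted over the list alone), and the list did not pass with camera (median 0.23, camera adjusted p = 0.247). Slc16a1 rose 2.47 fold (adjusted p = 0.000292) and Bdh2 fell 2.3 fold (adjusted p = 1.43e-05). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell 3.08 fold (adjusted p = 0.00121), and Gamt, of creatine synthesis, fell 3.15 fold (adjusted p = 1.48e-06).

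By the naming rule, the 6 largest increases were those of Cyp4a14, Gadd45b, Cyp4a10, Slc25a30, Npnt and Cyp4a31. Cyp4a14 rose 8.25 fold (log2 SE 0.93, adjusted p = 0.0418), a call that ended without AL replicate 3, any IF16 library or EOD replicate 1, 2, 3 or 4 (adjusted p up to 0.0962). Cyp4a10 rose 5.9 fold (adjusted p = 0.0135), Slc25a30, a mitochondrial carrier, 5.47 fold (adjusted p = 0.0121) and Npnt, a matrix protein, 5.23 fold (adjusted p = 0.0214, up to 0.066 without IF16 replicate 3 or 5 or EOD replicate 1; 8.73 fold without IF16 replicate 4). The 6 largest decreases by that rule were those of Thrsp, Hcn3, Chrna4, Cyp21a1, Erdr1 and Fam83f. Hcn3, an ion channel, fell 15.9 fold (adjusted p = 5.53e-05), Chrna4, a nicotinic receptor subunit, 14.8 fold (adjusted p = 0.000704) and Fam83f 11.6 fold (adjusted p = 0.000185). Cyp21a1 fell 14.2 fold (adjusted p = 0.0212, up to 0.0592 without IF16 replicate 5 or EOD replicate 1 or 2, and 9.23 fold without IF16 replicate 5). Its EOD level lay near the floor of 3 counts, so this fold is uncertain as well. Erdr1 fell 14 fold (adjusted p = 0.0326), a call that ended without IF16 replicate 2, 3, 4 or 5 or EOD replicate 1, 2, 3 or 4 (up to 0.0758). Mup7, a male-biased urinary protein with close copies, rose 4.75 fold (adjusted p = 0.0296), a call that ended without IF16 replicate 2, 3, 4 or 5 or EOD replicate 2 or 3 (up to 0.0777; 2.74 fold without EOD replicate 3).

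Of 45 ribosomal protein genes, 17 rose (26 when adjusted over the list alone), with a median of 0.34 (camera adjusted p = 5.92e-09, and adjusted p = 0.702 with an estimated correlation), and Rps9 rose 1.55 fold (adjusted p = 0.00588). Of 12 mitochondrially encoded genes, 11 fell (12 when adjusted over the list alone), with a median of -0.71 (camera adjusted p = 1.97e-07, and adjusted p = 0.652 with an estimated correlation), and mt-Co2 fell 1.68 fold (adjusted p = 0.00253). EOD replicate 5, at scores of 0.03 for the mitochondrial list, -0.05 for ribosomal proteins and -0.08 for the proteasome, lay within the IF16 range of each (-0.09 to 0.36, -0.24 to 0.17 and -0.24 to -0.05), apart from the other EOD libraries. Of 30 proteasome genes, 9 rose (10 higher and 1 lower when adjusted over the list alone), with a median of 0.16 (camera adjusted p = 0.000488, and adjusted p = 0.702 with an estimated correlation), and Psmd7 rose 1.59 fold (adjusted p = 0.00167). Of 19 antigen presentation genes, 6 fell (7 when adjusted over the list alone), with a median of -0.28 (camera adjusted p = 0.00047, and adjusted p = 0.702 with an estimated correlation). Tap2 fell 1.98 fold (adjusted p = 0.000125) and Psmb9 1.89 fold (adjusted p = 0.000703). EOD replicates 4 and 5, at 0.06 and -0.01, lay within the IF16 range of -0.23 to 0.36 for this list, and EOD replicates 1 to 3 at -0.68 to -0.32. Of 21 pericentral genes, 1 rose and 8 fell (2 and 9 when adjusted over the list alone), with a median of -0.3 (camera adjusted p = 0.0106, and adjusted p = 0.702 with an estimated correlation), and Cyp1a2 fell 2.32 fold (adjusted p = 1.43e-05).

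Of 19 heat shock genes, 6 rose (8 higher and 1 lower when adjusted over the list alone), with a median of 0.25 (camera adjusted p = 0.0214, and adjusted p = 0.809 with an estimated correlation; 0.0774 without IF16 replicate 1 and 0.0522 without EOD replicate 3). Hsp90ab1 rose 1.48 fold (adjusted p = 0.00664). Of 32 autophagy genes, 8 rose and 3 fell, as when adjusted over the list alone, with a median of 0.23 (camera adjusted p = 0.0348, and adjusted p = 0.702 with an estimated correlation; 0.0509 without IF16 replicate 4 and 0.0522 without EOD replicate 3). Gabarapl1 rose 2.58 fold (adjusted p = 1.72e-05) and Sqstm1, an autophagy receptor, 1.6 fold (adjusted p = 0.000423). Of 35 splicing factors, 1 rose and 6 fell, as when adjusted over the list alone, with a median of -0.2 (camera adjusted p = 0.0386, and adjusted p = 0.883 with an estimated correlation). The splicing call ended without IF16 replicate 4 (0.105) or 5 (0.0609) or EOD replicate 1 (0.134) or 3 (0.189). EOD replicate 5 was at a splicing score of 0.25, other EOD libraries at -0.46 to -0.02 and IF16 at -0.05 to 0.23, and in the heat shock and autophagy lists at -0.08 and -0.04, within the IF16 ranges of -0.24 to 0.22 and -0.14 to 0.02. Of 24 clock genes, 1 rose, Clock, by 1.97 fold (adjusted p = 0.000938), and 5 fell, among them Per2, a repressor, by 2.79 fold (adjusted p = 0.00125), with 2 and 7 when adjusted over the list alone. The clock list did not pass with camera (median -0.28, camera adjusted p = 0.195).

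In all, 2229 of 13837 genes (16.1%) differed between EOD and IF16 (1101 higher, 1128 lower), of which 401 by at least 2 fold, and 14 of 43 lists were called (6 up, 8 down). Of the 484 genes called in IF16 versus AL, 135 also differed between EOD and IF16, 98 of them further in the direction of the IF16 effect and 37 against it. The same IF16 libraries enter both comparisons, so choosing genes by the first pushes the second against it. The size of this push was not computed. The number of genes was 1418 without IF16 replicate 5, 1460 without EOD replicate 1 and 3383 without EOD replicate 5. With an estimated correlation 0 lists passed (camera, lowest adjusted p 0.652, 2 lists at an unadjusted p under 0.05), and with fry 10 did, among them 9 of the 14 called lists. The called lists that did not pass with fry were ribosomal proteins and proteasome (fry adjusted p = 0.0615 each), lipid droplets (0.165), heat shock (0.222) and splicing factors (0.272).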

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

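The 4 tests on AL replicates 4 and 5, the correlation of mitochondrial and ribosomal protein scores within groups and the 5 genes named below for opposite effects were chosen after the result was seen, as was the removal of mitochondrial genes as an alternative.

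Acute phase genes were high in AL replicates 4 and 5. S100a8 plus S100a9, abundant in neutrophils, reached 26.1 and 24.8 CPM against 5220 and 12600 CPM for Saa1 plus Saa2, a ratio of at most 0.00499. With Saa this high the ratio is low with or without leukocytes, and it covers neutrophils only, so leukocytes in these liver pieces stay open. Kupffer cell and macrophage scores were 0.14 and 0.39, against -0.75 to -0.03 in AL replicates 1 to 3. Scores of B and plasma cells were -0.7 and -0.66 against 0.38 to 0.93, and of T and NK cells -0.07 and 0.11 against -0.15 to 0.21. A swap with fasting libraries is argued against, by a narrow margin, by a score over 310 genes that changed in both regimens against AL replicates 1 to 3, without the acute phase list: AL replicates 4 and 5 were at -0.49 and -0.42, AL replicates 1 to 3 at -1.01, -0.96 and -0.8, and the lowest fasting library at 0.01, a gap of 0.43 (SD 0.21 over the 10 fasting libraries), and with pairs of fasting libraries held out of the choice of genes alike the smallest gap in 20 fits was 0.29 (SD 0.24). Single lists did not decide: the lower cholesterol synthesis score of the 2 libraries, 0.98, lay 0.55 above the highest fasting library (0.43, in IF16; highest in EOD -0.51), between the SD of 0.66 over the 10 fasting libraries and that of 0.39 over the 5 IF16 libraries, and their lipogenic scores, 0.35 and 0.25, lay within the IF16 range of -0.17 to 0.5. An acute phase response in these livers may also account for the pattern, and no biological explanation was tested, since the labels give none.

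Mitochondrially encoded transcripts were lower and ribosomal protein transcripts higher in EOD than in AL. With the mitochondrial genes removed before scaling, the median of the ribosomal protein genes was 0.62 (0.57 to 0.71 with 1 library left out), so their counts in the scaling did not make the difference. This outcome was close to fixed beforehand and is no separate evidence. The libraries were TMM-scaled, and mitochondrial transcripts took 11.49% of the counts in AL and 6.888% in EOD. A bias by gene length and GC content is argued against as the whole cause, since removing that trend left medians of 0.58 (0.55 to 0.67) for ribosomal protein genes and -0.97 (-1.25 to -0.84) for mitochondrial genes, against 0.62 and -0.81 before. A gradient between libraries, such as one of RNA quality, stays open: within groups the scores correlated at -0.39 (permutation p = 0.295, adjusted over 2 relations 0.295), and at 0.2 without EOD replicate 5 and AL replicate 2. The feeding regimen may account for the pattern and was not separated from such a gradient.

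Other splits of the 10 libraries of each comparison were tested, 100 per comparison with the real one included. For the number of genes, in each comparison 1 split of the 100, the real one, gave as many, which is the smallest share that 100 splits allow. The counts were 484 genes against 8 in the highest other split for IF16 versus AL, 4867 against 2592 for EOD versus AL and 2229 against 1313 for EOD versus IF16. This argues against chance at that level only, and only if each library is a separate mouse. The other splits mix both groups, so a difference between them counts as spread there, and their low counts are not those of unchanged groups. For the number of gene lists chance cannot be excluded: 43 splits gave as many as the 14 lists of IF16 versus AL (highest other 23), 47 as many as the 13 of EOD versus AL (22) and 11 as many as the 14 of EOD versus IF16 (19).

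A total of 5 genes passed in both fasting groups with opposite signs against the same AL libraries. As they were picked for opposite signs, a difference between EOD and IF16 follows from the choice, and its size is given without a p-value. The SE beside it comes from the F statistic of the same difference and is not to be read as a test. Sgk2, a kinase (chromosome 2, 162987330 to 163014127), was at -1.25 in IF16 and 1.04 in EOD versus AL, a difference of 2.29 (SE 0.21). Nat8, an acetyltransferase (chromosome 6, 85830388 to 85832082), was at 0.88 and -1.35, a difference of -2.23 (SE 0.15). Gnai1, a G protein subunit, was at -0.82 and 0.45, a difference of 1.27 (SE 0.16), and its EOD call ended without AL replicate 2, 4 or 5 or EOD replicate 1, 2 or 4 (adjusted p up to 0.0771). Fam134b, a receptor of endoplasmic reticulum autophagy, was at -0.53 and 0.47, a difference of 0.99 (SE 0.13), and its IF16 call ended without AL replicate 4 or 5 or IF16 replicate 2, 3 or 5 (up to 0.0752). Agxt, which detoxifies glyoxylate, was at -0.48 and 0.36, a difference of 0.84 (SE 0.12). Its IF16 call ended without AL replicate 1, 3, 4 or 5 or IF16 replicate 2, 3 or 5 (up to 0.109), and its EOD call without AL replicate 2 or 4 or EOD replicate 2 (up to 0.0692).

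In 18 of 354 groups of 5 libraries, 1 library lay far from the others, where chance gives about 17.7 at a limit of 0.71 for its gap over the whole range. The list scores were those of the proteasome in AL replicate 2 (-0.21, others 0.05 to 0.14, ratio 0.743) and of mitochondrially encoded transcripts in EOD replicate 5 (0.03, others -0.78 to -0.6, ratio 0.778). In AL replicate 2 the log2 CPM of Chrna4 was 4.42 (others 2.38 to 2.96, ratio 0.718), of Gabarapl1 7.28 (7.8 to 7.97, 0.749), of Nat8 4.98 (5.36 to 5.48, 0.759) and of Psmd14 4.97 (5.58 to 5.74, 0.796). Igfbp2 was at 7.84 in AL replicate 1 (8.39 to 8.62, 0.71), and in AL replicate 3 Cyp2c37 was at 8.77 (7.99 to 8.17, 0.776) and Cyp7a1 at 6.18 (5.35 to 5.55, 0.76). Among the IF16 libraries, Cyp7a1 was at 6.79 in replicate 1 (5.29 to 5.62, 0.78), Gprc5b at -2.71 in replicate 2 (-2 to -1.73, 0.726), Psmb9 at 3.97 (4.58 to 4.77, 0.771) and Saa1 at 7.38 (4.38 to 5.22, 0.722) in replicate 4, and Per2 at 5.97 in replicate 5 (5.07 to 5.31, 0.736). In EOD replicate 5, Lepr was at 1.86 (3.17 to 3.65, 0.73) and mt-Atp6 at 7.93 (7 to 7.25, 0.725). Gys2 was at 5.97 in EOD replicate 1 (6.56 to 6.79, 0.712) and Serpina3m at 7.99 in EOD replicate 3 (7.53 to 7.67, 0.711).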

How the results depend on the processing

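Leaving out AL replicates 4 and 5 and removing the mitochondrial genes were chosen after the result was seen. With DESeq2 size factors, all 143 named gene results and 41 called lists kept direction and side of the threshold. Named gene results that lost their call numbered 13 with no filter on low counts, 12 with limma on log2(FPKM + 1) and 9 with the 2 groups compared alone, and summed over the 15 leave-one-out fits, 144 calls of named genes and 47 calls of lists were lost. The number of genes in IF16 versus AL was 936 with the DESeq2 Wald test and 261 with limma on log2(FPKM + 1) with no filter. With 1 library left out it was 241 to 619 (269, 241 and 254 without IF16 replicates 2, 3 and 5). In EOD versus IF16 it was 1418 to 3383 (1418 without IF16 replicate 5, 1460 without EOD replicate 1, 3383 without EOD replicate 5), and the genes shared by both regimens numbered 212 to 523 (229, 212 and 228 without IF16 replicates 2, 3 and 5). For EOD versus AL, no alternative moved the number by over 1.5 times. Lists called with camera and an estimated correlation were 0, 0 and 0 (3, 2 and 2 at an unadjusted p under 0.05), with fry 3, 20 and 10, and with no filter on low counts 20 in EOD versus AL. Of the lists called in the main camera test, 3, 13 and 9 passed with fry. The correlation of the fasting effects was 0.551 with no filter and 0.462 with the AL libraries split, where 144 genes were shared. Without AL replicates 4 and 5, the numbers of genes were 368, 4311 and 2382, with 242 of the 484 of IF16 versus AL kept. There the sign turned for the acute phase list (0.22) and Saa2 (0.21) in IF16 versus AL and for Saa1 (0.11) in EOD versus AL, and 18 other named gene results lost their call. Of the named genes called, 14 of 43 in IF16 versus AL, 5 of 52 in EOD versus AL and 0 of 47 in EOD versus IF16 no longer held, Saa1 included. Not all of these losses are given beside the gene. Where libraries were left out, their smaller number may account for some losses, and no cause of the losses was tested. With the replicate number as a block, genes numbered 492, 4809 and 2226 and lists 14, 11 and 13, and 15 named gene results and 3 lists lost their call. Deviations of libraries with the same number correlated at -0.13 to 0.218 and 3 of 15 pairs matched best to their own number, so the numbers were not read as pairs. Recovery of changes of 1.5 fold in simulated counts, 25.8% to 31.3%, limits what smaller changes can be seen at this depth.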

Other observations

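Both tests on clock genes below were chosen after the result was seen, and the other values here come from lists fixed in advance.

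Several gene groups had members past the threshold in EOD versus AL without a call for the list with camera. Over all tested genes 35.2% passed in that comparison. Shares near or under this, as for immediate early genes, splicing factors, the urea cycle and gluconeogenesis, show no response of the group by themselves. Of those below, lipoproteins (fry adjusted p = 0.00192), cell cycle (0.00528), glycolysis (0.00188), glycogen (0.00217) and NRF2 targets (0.00124) passed with fry. The NRF2 scores were 0.39 and 0.38 in AL replicates 4 and 5, -0.17 to -0.13 in the other AL libraries and -0.12 to 0.07 in EOD. The lower direction of that list thus rests on AL replicates 4 and 5. Of 25 lipoprotein and lipid transport genes, 10 rose and 2 fell (11 and 2 when adjusted over the list alone; median 0.25, camera adjusted p = 0.0736). Of 35 splicing factors, 2 rose and 9 fell (median -0.24, camera adjusted p = 0.0747), and of 23 immediate early genes, 8 fell (median -0.57, camera adjusted p = 0.0747). Of 33 cell cycle genes, 5 rose and 10 fell (median -0.34, camera adjusted p = 0.141). Of 22 glycolysis genes, 2 rose and 9 fell (median -0.27, camera adjusted p = 0.0852), and of 16 glycogen genes, 2 rose and 5 fell (median -0.17, camera adjusted p = 0.147). Of 18 female-biased genes, 7 rose and 4 fell (median 0.84, camera adjusted p = 0.0765), with scores of -1.38 and -1.82 in AL replicates 4 and 5, 0.1 to 0.37 in the other AL libraries and -0.21 to 0.88 in EOD. The gluconeogenesis and fasting response list had 2 of 23 genes risen and 1 fallen (median 0.11, camera adjusted p = 0.542), and 1 risen in IF16 versus AL (median 0.07, camera adjusted p = 0.205). The urea cycle (3 of 10 risen, median 0.08, camera adjusted p = 0.441), bile acid (8 of 25 risen and 5 fallen, 0.08, 0.491), citric acid cycle (5 of 21 and 7, -0.1, 0.816), NRF2 (6 of 20 and 4, -0.12, 0.822) and periportal lists (5 of 20 and 4, 0.03, 0.691) were not called with camera either. Of 33 amino acid catabolism genes, 7 rose and 9 fell, with a median of -0.06 and a mean of 0.01. In the male-biased list, 4 of 26 rose and 7 fell, with a median of 0.03 and a mean of -0.4. One-carbon genes (7 rose and 7 fell of 25) had a median of -0.08 and a mean of 0.02, fibrosis genes (3 and 2 of 24) a median of -0.02 and a mean of 0.01, and cholangiocyte markers (3 and 0 of 12) a median of -0.18 and a mean of 0.03. In EOD versus IF16 the sign of the median also differed from that of the mean or the test for amino acid catabolism (-0.09 and 0.06), xenobiotic metabolism (0.07 and -0.06), NRF2 targets (0.18 and 0.05, test lower) and the unfolded protein response (-0.09 and 0.01). In IF16 versus AL it differed for glycolysis (0.02 and -0.1), B and plasma cells (-0.01 and -0.17, test higher) and hepatocyte markers (0.05, with a mean at the rounding limit).

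Among the cell type lists tested, that of sinusoidal endothelium alone was called with camera or fry, in both comparisons with AL and not in EOD versus IF16 (median 0.12, camera adjusted p = 0.65). In EOD versus AL, camera adjusted p was 0.415 for Kupffer cells and macrophages (median 0.18), 0.169 for stellate cells and fibroblasts (0.29), 0.376 for T and NK cells (-0.19, with 2 of 13 genes fallen), 0.401 for B and plasma cells (-0.37, with 2 of 10 fallen) and 0.848 for erythroid cells (0.02). Of the lists with under 5 tested genes, neutrophil markers fell in 1 of 4 genes in IF16 and 3 of 4 in EOD versus AL, and adipocyte markers in 2 of 4 and 3 of 4. Over all tested genes 3.5% and 35.2% passed in these comparisons. The neutrophil gene in IF16 was S100a8, whose call ended without AL replicates 4 and 5. Of the pancreas markers, 1 gene was tested and it fell in EOD versus AL, and of the 2 tested genes of kidney, muscle, gallbladder or gut, 1 fell in EOD versus IF16. None of the 4 sex-linked genes tested passed in edgeR in any comparison.

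Clock genes that peak at opposite times moved apart in EOD. The Arntl set had a median of 1.47 versus AL, with 5 of 6 genes risen, and the Dbp set a median of -1, with 7 of 11 fallen, a difference of 2.47. A candidate explanation is that the groups were at different clock phases at sampling, which the difference would also show if the regimen itself shifted the clock, and the hour of sampling is not in the labels. Lipogenic scores that follow the clock state were tested within groups (r = -0.29, permutation p = 0.204, adjusted over 2 relations 0.295; -0.05 without IF16 replicates 4 and 1), which leaves that relation open. The same sets stood at 0.92 and -0.39 in IF16 versus AL, with 3 of 6 genes risen and 1 of 11 fallen. In EOD versus IF16 they stood at 0.81 and -0.49, with 1 gene risen and 1 fallen in the Arntl set and 2 fallen in the Dbp set.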
